A study of Mus musculus with 22 samples.

How the data were processed

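RNA was taken from frozen livers of male C57BL/6 mice, 22 samples in 6 groups given by the labels' genotype and age: WT and Slc10a1 KO at 4 weeks (3 and 3), 8 weeks (4 and 6) and 20 months (3 and 3). Per the labels' protocols, poly(A) RNA was selected on beads, fragmented and reverse transcribed, and the libraries were sequenced on an Illumina HiSeq platform. The deposited values are raw read counts per Ensembl gene, 1 table per sample. Per the submitters' processing notes, reads were aligned to GRCm38 with HISAT2 2.0.4 and counted with HTSeq 0.6.1p1; the annotation release, the strand setting and any read filter are not stated. Per the file names, the 4-week libraries were paired-end and the others single-end, so a count stands for a read pair at 4 weeks and for a read at the other ages. Each table had 47729 gene lines and 5 summary lines. The lines for unaligned and multiply aligned reads were 0 in all 22 tables, so no reads were recorded as such. Whether they were removed before counting is not stated. Genes with near-identical copies (Mup, Sult2a, Ugt1a and Ugt2b, serpin and globin clusters) may therefore be miscounted to an unknown degree. With the strand setting unknown, reads of overlapping genes on opposite strands cannot be assigned with certainty.

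Gene symbols came from the GENCODE mouse release M21 annotation by Ensembl identifier, for 47310 of 47729 genes; 419 had none. Counts assigned to genes totalled 5496425 to 6956124 per library at 4 weeks, 18950112 to 26066897 at 8 weeks and 18032355 to 26789350 at 20 months. The limit that a count of 0 allows, 3 counts, corresponded to 0.103 to 0.640 CPM per library, which covers counting error alone. Reads outside genes made up 6.13% to 17.78% of the reads recorded (in genes, outside genes or ambiguous), and ambiguous reads 3.8% to 7.3%. Pairs of libraries of 1 group were checked for duplication: the smallest chi-square per degree of freedom was 7.65, far above the value near 1 that repeated sequencing of 1 library gives.

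Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries scaled by TMM, dispersions estimated and groups compared by the 2-sided quasi-likelihood F-test, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p over all genes tested. KO and WT were compared within each age in a fit of that age alone (biological coefficient of variation 0.266 at 4 weeks, 0.321 at 8 weeks, 0.339 at 20 months). WT livers were compared between 4 and 8 weeks (0.159) and between 8 weeks and 20 months (0.273). Whether the KO effect differed among ages was tested in 1 fit of the 22 libraries with 6 group means (0.324), jointly and by pairs of ages. The SE of a log2 fold change is its size divided by the square root of F. Genes passing in the same direction at all 3 ages were counted, and overlaps between ages tested by the one-sided Fisher exact test for more overlap than expected. CPM values use TMM factors of all 22 libraries, and scores of lists per library average log2 CPM with a prior count of 2, set against the WT mean of the age. For a gene with 0 counts in a whole group, bounds were computed against 3 counts over the libraries of that group, and setting such genes to their bound moved no list median.

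Before the data were examined, 29 gene lists (598 symbols, 3 not matched) were fixed. They covered sulfation, bile acid synthesis, transport and signalling, targets of CAR and PXR, glucuronidation, cholesterol synthesis, fatty acid synthesis and oxidation, male-biased and female-biased liver genes, acute phase, interferon response, fibrosis, cell cycle, NRF2 targets, endoplasmic reticulum stress, circadian genes, and oncofetal and tumour genes. The rest were markers of cholangiocytes, macrophages, lymphocytes, neutrophils, endothelium, stellate cells, erythroid cells, pericentral and periportal hepatocytes, and adipose, pancreas and muscle tissue. Lists with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, 2-sided and adjusted over the lists of an age. Camera was repeated with a correlation estimated for each list, and fry tested whether the genes of a list moved on balance in 1 direction, without reference to other genes. Members were also adjusted over the list alone. The design, the alternatives and a rule for the genes named were fixed at the same time. The rule takes a core panel of 18 genes in each comparison of KO with WT. It adds, per such comparison, up to 6 higher and 6 lower genes with the largest change among those past the threshold with a mean log2 CPM of at least 1, all KO libraries beyond all WT libraries (which chance alone gives for 10% of genes at 3 against 3) and a symbol that is not a predicted-gene name. From each list with at least 3 members past the threshold it takes the 2 members with the smallest adjusted p. It further takes 6 genes from the joint test of ages and 4 higher and 4 lower genes for each age comparison in WT. Sult1a1, Akr1d1, Cyp2a4, Hal, Gls2, Arg1, Cps1, Aldh1b1, and the clock gene Arntl were chosen after their values were seen. So were the acute-phase genes Saa1 and Lcn2, Igfbp1, Asns, Atf4, Mlxipl, Hamp2, Gm17167 and Gm5859, and genes named at 1 age that were carried over to another. Some genes that the rule takes are not reported here, while the counts of genes and the tests of lists include them.

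The tests were tried on simulated counts with 200 genes changed, drawn from the means and library sizes of the real genes. At a 2-fold change 19.4% of changed genes were recovered at 4 weeks, 51.0% at 8 weeks and 5.0% at 20 months, and at a 4-fold change 89.9%, 90.9% and 70.0%. For WT at 8 against 4 weeks recovery was 63.0% and 94.0%, for 20 months against 8 weeks 35.0% and 85.0%, and for the joint test of ages 4.0% and 52.0%. False calls numbered 2 to 10 per simulation, and a planted list of 20 genes was recovered at each age with 0 false lists. Simulated genes were drawn independently of one another, whereas the estimated correlation within a real list reached 0.932 (male-biased genes at 8 weeks). The simulation therefore does not show how often lists of correlated genes are called falsely. Each planted change was also the same in every library of the changed group. The recovery at 8 weeks therefore does not hold for genes that changed in only some KO libraries. Cyp2b10, for example, had a log2 fold change of 5.95 there and did not pass in edgeR (adjusted p = 0.474). Alternatives changed the scaling, the filter, the dispersion, the fold threshold, the most abundant genes, the fit, the replicate number as a block, the test (DESeq2 1.42.0) and the inter-gene correlation, and left out each library in turn. A fit by limma voom with a quality weight per group and the 20-month comparison without WT libraries 1 and 2 were added after the data were seen. In the latter the lone WT library is assumed to vary like the other groups. Figures were drawn with Python and matplotlib 3.10.9.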

Results

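Gene expression was measured by RNA sequencing of poly(A) RNA from the livers of male C57BL/6 mice. The mice were wild type (WT) or carried a knockout (KO) of Slc10a1, which encodes NTCP, the sodium-dependent transporter that takes conjugated bile acids from portal blood into hepatocytes. Livers came from mice of 4 weeks (3 WT, 3 KO), 8 weeks (4 WT, 6 KO) and 20 months (3 WT, 3 KO), 22 libraries in all. Counts assigned to genes were 5496425 to 6956124 per library at 4 weeks, 18950112 to 26066897 at 8 weeks and 18032355 to 26789350 at 20 months. The number of genes with at least 1 count was 16426 to 16996 at 4 weeks, 21177 to 22832 at 8 weeks and 19907 to 22704 at 20 months. The p-values of genes rest on the spread between these samples. The labels give 1 liver sample per library and nothing on litters or cages. List p-values by camera with the preset inter-gene correlation rest on the spread of test statistics across genes. A small list p-value therefore does not measure how far the livers agree. With libraries of an age regrouped regardless of genotype, the median was 10 lists called at 4 weeks, 9 at 8 weeks and 16 at 20 months. The real groups gave 14, 12 and 12. Levels below are CPM values, counts scaled to library totals multiplied by TMM factors, given as mean ± SD over the libraries of a group, and fold changes are on the log2 scale with their standard error (SE).

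The targeted gene, Slc10a1 (ENSMUSG00000021135, chromosome 12, 80953183 to 80968705 in GRCm38), was lower in every KO library than in every WT library of its age. At 4 weeks it stood at 657 ± 58 CPM in WT (n = 3) and 168 ± 76.2 CPM in KO (n = 3), a log2 fold change of -1.93 (SE 0.33, adjusted p = 0.0117). The 8-week values were 456 ± 15.9 CPM (n = 4) and 68.1 ± 16.2 CPM (n = 6), with a log2 fold change of -2.72 (SE 0.16, adjusted p = 9.00e-05). At 20 months the values were 271 ± 109 and 96.1 ± 6.04 CPM (n = 3 each). The difference did not pass in edgeR (log2 fold change -1.49, SE 0.32, adjusted p = 0.821) but passed in DESeq2 (-1.49, adjusted p = 0.0101). The counts cover the whole gene and the labels do not say which part was deleted, so reads from a part left in place are included. Leaving out WT library 2 or 3 or KO library 3 ended the 4-week call (adjusted p = 0.0532, 0.057 and 0.0549).

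**Figure D1:**
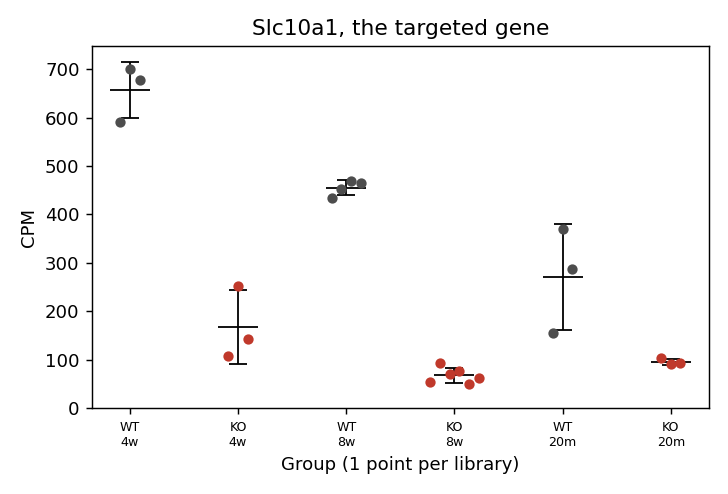
Slc10a1 level in CPM (linear axis) for each of the 22 libraries by genotype and age, 1 point per library, with horizontal bars at the mean and error bars of 1 SD. All KO libraries lie below all WT libraries of the same age, with the smallest distance at 20 months (WT 154 to 370.2, KO 92.3 to 103).

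The 4-week comparison asks what the loss of hepatic bile acid uptake does to liver transcripts in young mice, with sulfation of bile acids as the subject the series names. Some sulfotransferases rose. Sult1e1, the estrogen sulfotransferase, went from 2.53 ± 1.51 to 1177 ± 636 CPM (log2 fold change 8.88, SE 0.67, adjusted p = 2.58e-04; n = 3 per group). Sult1b1, which sulfates thyroid hormones, went from 19.3 ± 1.14 to 85.4 ± 7.80 CPM (log2 fold change 2.18, SE 0.18, adjusted p = 4.02e-04). Sult2a1, a hydroxysteroid and bile acid sulfotransferase, was nearly absent in WT livers (0.501 ± 0.405 CPM) and reached 956 ± 882 CPM in KO livers (range 8.40 to 1752; adjusted p = 0.0125). Its paralogs Sult2a2 (0.179 to 206 ± 184 CPM; adjusted p = 0.00799) and Sult2a6 (0.0621 to 42 ± 37.3 CPM; adjusted p = 0.0138) rose as well. Reads shared between Sult2a paralogs leave the level of each single member uncertain. Sult1a1, a phenol sulfotransferase, rose by a log2 fold change of 1.48 (SE 0.26, adjusted p = 0.0133). Sult2a8, another bile acid sulfotransferase of mouse liver, stood at 765 ± 79.3 CPM in WT and 134 ± 136 CPM in KO and did not pass the test (log2 fold change -2.47, SE 0.70, adjusted p = 0.0553). Papss2, which makes the sulfate donor, did not pass either (adjusted p = 0.321), and Sult3a1 had too few counts to be tested. Of 14 sulfation genes tested, 6 rose, 0 fell and 8 did not pass, against 7 higher and 2 lower adjusted over the list alone. The list was called higher by camera (adjusted p = 1.19e-04) but not with an estimated correlation (adjusted p = 0.0899). The calls of Sult2a1 (adjusted p up to 0.0658), Sult2a2 (0.051) and Sult2a6 (0.0762) were lost without WT library 3. Those of Sult2a1 and Sult2a6 were also lost without WT library 2, and that of Sult2a6 without WT library 1. Sult2a8 was called lower without KO library 1 or 2 (adjusted p = 0.0175 and 0.00878).

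**Figure D2:**
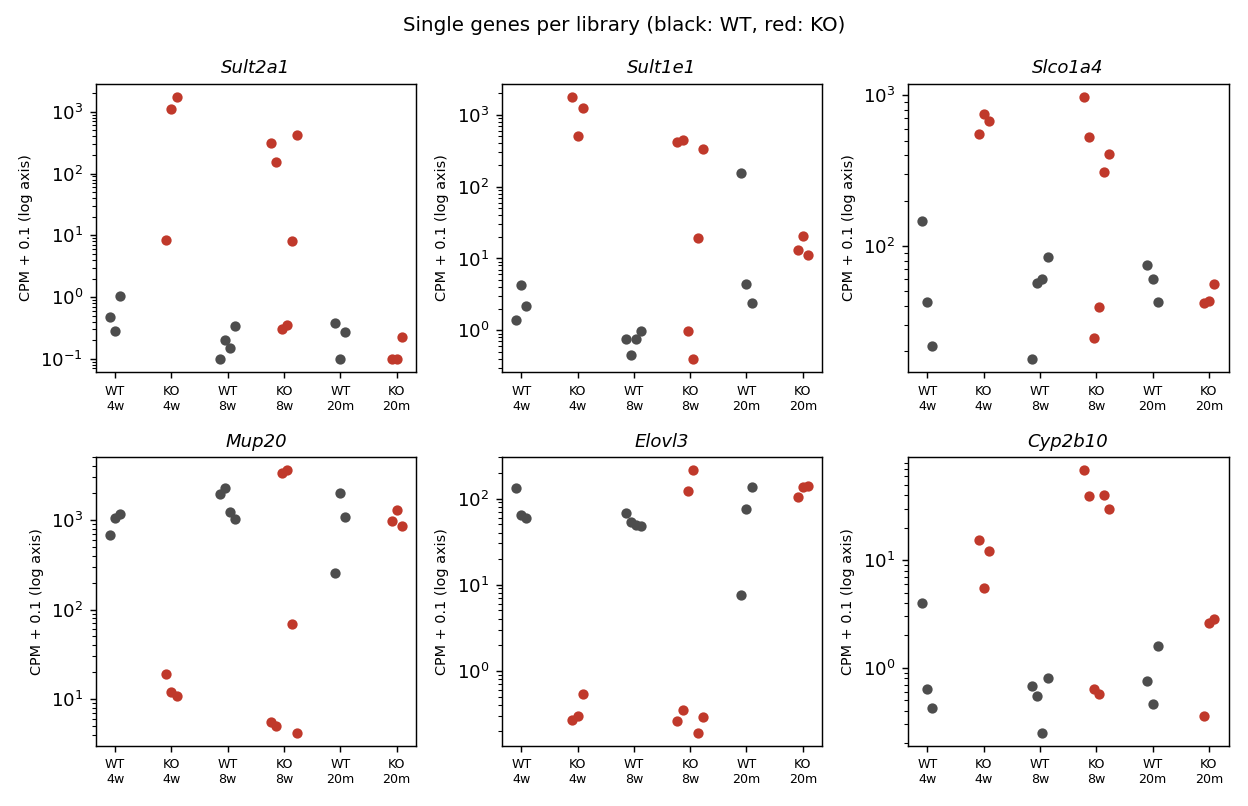
Levels of 6 genes in each of the 22 libraries, as CPM plus 0.1 on a log axis, 1 point per library, WT in black and KO in red, by age. At 4 weeks all KO libraries lie above WT for Sult2a1, Sult1e1, Slco1a4 and Cyp2b10 and below it for Mup20 and Elovl3, and the 6 KO libraries of 8 weeks spread widely.

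Among genes of bile acid transport at 4 weeks, Slco1a1, an organic anion uptake carrier of hepatocytes, fell from 685 ± 249 to 17.3 ± 6.80 CPM (log2 fold change -5.27, SE 0.43, adjusted p = 3.59e-04; n = 3 per group). Slco1a4, a related carrier, rose from 70.3 ± 67 to 658 ± 95.5 CPM (log2 fold change 3.25, SE 0.64, adjusted p = 0.0183). Slco1b2, a carrier of unconjugated bile acids, fell (log2 fold change -1.14, SE 0.25, adjusted p = 0.0268). The canalicular bile salt export pump Abcb11 (-0.80, SE 0.30, adjusted p = 0.119) and the basolateral exporter Abcc4 (0.87, SE 0.36, adjusted p = 0.150) did not pass. Of 20 transport genes tested, 1 rose, 3 fell and 16 did not pass (1 higher and 5 lower adjusted over the list alone). Camera called the transport list lower (adjusted p = 0.0140), but not with an estimated correlation (adjusted p = 0.207). In bile acid synthesis, Cyp7b1, the oxysterol hydroxylase of the alternative pathway, fell from 46.3 ± 4.88 to 4.17 ± 0.816 CPM (log2 fold change -3.42, SE 0.23, adjusted p = 1.50e-04). Hsd17b6, a steroid dehydrogenase, fell by 3.86 on the log2 scale (SE 0.59, adjusted p = 0.00811). Akr1d1, the bile acid 5-beta-reductase, was the only synthesis gene that rose (1.44, SE 0.31, adjusted p = 0.0233). The rate-limiting enzyme Cyp7a1 (0.40, SE 0.41, adjusted p = 0.548), Cyp8b1 (adjusted p = 0.868) and Cyp27a1 (adjusted p = 0.242) did not pass. Of 19 synthesis genes tested, 1 rose, 3 fell and 15 did not pass (3 higher and 4 lower adjusted over the list alone), and the list was not called (adjusted p = 0.163). None of 17 bile acid signalling genes passed in edgeR, over all genes or adjusted over the list alone (list adjusted p = 0.212). Among them were Nr0b2, a repressor induced by the bile acid receptor (-0.54, SE 0.54, adjusted p = 0.547), and Nr1h4, the receptor itself (adjusted p = 0.933). Without WT library 1 the transport list was no longer called (adjusted p = 0.0954). Slco1a4 lost its call without WT library 2 or 3 or KO library 3 (adjusted p up to 0.0845), and Slco1b2 without any of the 3 WT libraries or KO library 3 (adjusted p up to 0.117).

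Genes of foreign compound metabolism moved in both directions at 4 weeks. Gsta2, a glutathione transferase, rose from 3.08 to 25.5 CPM (log2 fold change 3.09, SE 0.38, adjusted p = 0.00337; n = 3 per group). Cyp2b10, a cytochrome P450 under the receptor CAR, rose from 1.58 ± 2.02 to 10.9 ± 5.01 CPM (log2 fold change 2.84, SE 0.74, adjusted p = 0.0439). Cyp3a11, a target of the receptor PXR, did not pass (adjusted p = 0.866). Ugt1a9, a glucuronosyltransferase, fell (log2 fold change -2.61, SE 0.35, adjusted p = 0.00502). Of 22 targets of CAR and PXR tested, 6 rose, 2 fell and 14 did not pass (10 higher and 2 lower adjusted over the list alone). They were called higher as a list (adjusted p = 0.00350), but not with an estimated correlation (adjusted p = 0.416). Their scores were 0.477, -0.215 and -0.262 in WT libraries 1 to 3 and 0.487, 1.235 and 0.875 in KO libraries 1 to 3. KO library 1 thus stood level with WT library 1. Of 17 glucuronidation genes, 0 rose, 7 fell and 10 did not pass (2 higher and 9 lower adjusted over the list alone). Ugt2b1 dropped from 684 ± 71.4 to 163 ± 3.63 CPM (log2 fold change -2.03, SE 0.20, adjusted p = 0.00130) and Ugt2b38 fell too (log2 fold change -4.79, SE 0.40, adjusted p = 4.02e-04). Both belong to a cluster of close paralogs that share reads. That list was called lower (adjusted p = 8.04e-06; adjusted p = 0.0899 with an estimated correlation). Among 21 NRF2 targets 3 rose, 1 fell and 17 did not pass (4 higher and 3 lower adjusted over the list alone), and the list was not called (adjusted p = 0.405). Hmox1, heme oxygenase, was among those that rose (log2 fold change 2.35, SE 0.32, adjusted p = 0.00560). Of 22 genes of endoplasmic reticulum stress 2 rose and 20 did not pass, also adjusted over the list alone, and the list was not called (adjusted p = 0.385). Cyp2b10 lost its call without WT library 2 or 3 or KO library 3 (adjusted p up to 0.154), and Cyp3a11 was called higher without WT library 1 (adjusted p = 0.0451).

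Genes that male mouse liver expresses above female liver fell together at 4 weeks. Elovl3, a fatty acid elongase, dropped from 86 ± 41.2 to 0.265 ± 0.141 CPM (log2 fold change -8.23, SE 0.55, adjusted p = 1.50e-04; n = 3 per group). Mup20, a major urinary protein, dropped from 969 ± 252 to 13.9 ± 4.59 CPM (log2 fold change -6.08, SE 0.37, adjusted p = 1.20e-04). Other urinary protein genes fell to low levels: Mup7 went from 996 ± 619 to 1.04 ± 0.627 CPM (adjusted p = 1.50e-04) and Mup14 from 417 ± 129.5 to 0.474 ± 0.462 CPM (adjusted p = 9.96e-05). Mup8, Mup1 and Mup12 had 0 counts in all 3 KO libraries. Against a floor of 3 counts over the KO group (0.192 CPM), they were at least 188-fold, 165-fold and 109-fold lower than in WT. Mup genes are near-identical copies that share reads, so the level of each copy is uncertain. Serpina4-ps1, a pseudogene of the serpin cluster, fell from 78.2 ± 70.1 CPM to 0.0670 CPM. Of 24 male-biased genes tested, 0 rose, 21 fell and 3 did not pass (23 lower adjusted over the list alone), with a median log2 fold change of -3.34. This was the only list of the 26 tested at 4 weeks that kept its call with an estimated correlation (adjusted p = 9.82e-57; adjusted p = 0.0177 with an estimated correlation). Genes with higher expression in female liver were split. Atp6v0d2, a proton pump subunit, rose (log2 fold change 4.26, SE 0.34, adjusted p = 3.59e-04), while Cyp2a4 fell (-2.18). Of 18 tested, 6 rose, 2 fell and 10 did not pass (6 higher and 3 lower adjusted over the list alone). Female-biased genes were called higher as a list (adjusted p = 6.92e-04), but not with an estimated correlation (adjusted p = 0.378). Their score in KO library 1 (0.124) lay within the WT range (-0.267 to 0.267), with 1.638 and 1.254 in KO libraries 2 and 3. Outside the lists, Slc4a9, an anion exchanger, rose from 0.0621 to 15.4 ± 4.10 CPM (adjusted p = 3.40e-04). Tppp3, a tubulin-binding protein, rose from 0.106 to 20.3 ± 23 CPM (adjusted p = 0.0138), a call lost without WT library 2 or 3 (adjusted p up to 0.0807).

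**Figure D3:**
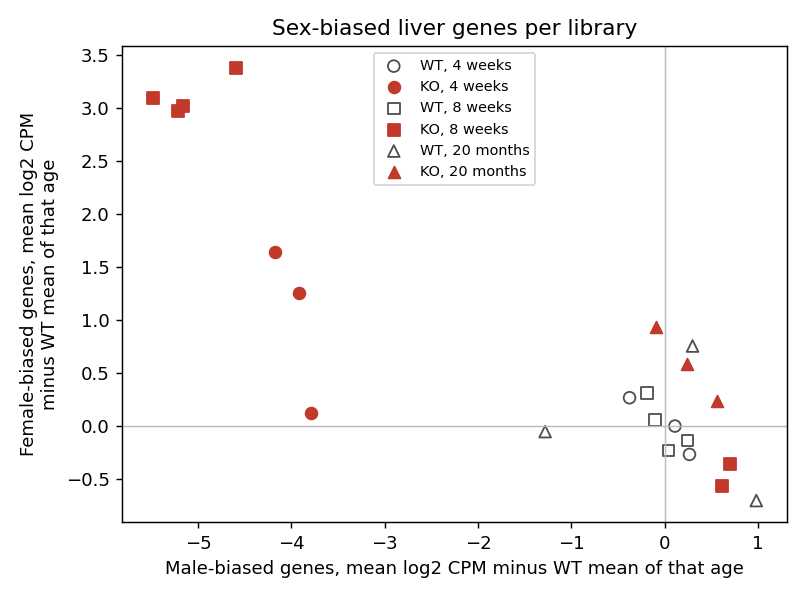
Score of the male-biased genes (horizontal axis) and of the female-biased genes (vertical axis) in each library, both in log2 CPM averaged over the list and set against the WT mean of that age, where open symbols are WT, filled red symbols KO, with a shape for each age. The 3 KO libraries of 4 weeks lie at male-biased scores of -3.79, -4.18 and -3.92, and the 6 KO libraries of 8 weeks at -5.16, -5.21, 0.619, 0.701, -4.59 and -5.48.

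In lipid metabolism at 4 weeks, Lss, which closes the sterol ring, rose (log2 fold change 1.5, SE 0.26, adjusted p = 0.0124; n = 3 per group). Of 23 cholesterol synthesis genes 4 rose, 0 fell and 19 did not pass (5 higher adjusted over the list alone). As a list they were called higher (adjusted p = 3.89e-04), but not with an estimated correlation (adjusted p = 0.542). Vnn1, a pantetheinase under PPAR-alpha, fell (log2 fold change -4.61, SE 0.85, adjusted p = 0.0153) and Pdk4, which brakes pyruvate oxidation, rose (log2 fold change 2.74, SE 0.69, adjusted p = 0.0412). These belonged to 27 fatty acid oxidation genes, of which 2 rose, 2 fell and 23 did not pass (2 higher and 2 lower adjusted over the list alone). Camera called the oxidation list lower (adjusted p = 0.0183; adjusted p = 0.658 with an estimated correlation). KO library 1 stood apart in both lists: cholesterol synthesis scored -0.497, 1.77 and 1.353 in KO libraries 1 to 3 (WT -0.36 to 0.199) and oxidation -2.528, -0.233 and -0.567 (WT -0.245 to 0.147), in log2 CPM against the WT mean. Of 18 fatty acid synthesis genes 0 rose, 2 fell and 16 did not pass (3 lower adjusted over the list alone; list not called, adjusted p = 0.0941). The oxidation list lost its call without WT library 1 (adjusted p = 0.0514) or KO library 1 (0.249), and the fatty acid synthesis list was called lower without WT library 1 (0.0458) or KO library 2 (0.00271). All 3 named genes lost theirs without WT library 2 or 3, with adjusted p up to 0.0686 for Lss, 0.0651 for Vnn1 and 0.154 for Pdk4; KO library 3 did the same for the last 2, and WT library 1 for Pdk4.

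Interferon response genes fell at 4 weeks. Irf7, a transcription factor of that response, went from 30.4 ± 6.67 to 3.38 ± 0.613 CPM (log2 fold change -3.13, SE 0.27, adjusted p = 4.24e-04; n = 3 per group). Rtp4, another interferon-induced gene, fell by 2.08 on the log2 scale (SE 0.28, adjusted p = 0.00516). Of 23 genes tested, 0 rose, 17 fell and 6 did not pass (22 lower adjusted over the list alone), with a median log2 fold change of -1.95. This list was called lower (adjusted p = 2.32e-18), but not with an estimated correlation (adjusted p = 0.0957). Among 27 acute-phase genes, 4 rose, 4 fell and 19 did not pass (5 higher and 4 lower adjusted over the list alone; list not called, adjusted p = 0.500). The serum amyloid genes Saa3 (log2 fold change -3.88, SE 0.48, adjusted p = 0.00364) and Saa4 (log2 fold change -4.72, SE 0.62, adjusted p = 0.00465) fell. Marco, a scavenger receptor of macrophages, rose (log2 fold change 2.63, SE 0.31, adjusted p = 0.00325) while Clec4f, a Kupffer cell lectin, fell (log2 fold change -1.32, SE 0.25, adjusted p = 0.0155). Of 14 macrophage markers 1 rose, 4 fell and 9 did not pass (1 higher and 7 lower adjusted over the list alone). These markers were called lower as a list (adjusted p = 0.00467), but not with an estimated correlation (adjusted p = 0.421). Endothelial markers counted 0 higher, 3 lower and 15 not passing of 18 (4 lower adjusted over the list alone). Flt4, a receptor of lymphatic and sinusoidal endothelium (-1.09), and Cdh5, the endothelial cadherin (-0.98), were among those that fell. Here the list call was downwards (adjusted p = 0.0156; adjusted p = 0.511 with an estimated correlation). In the fibrosis list, the collagen gene Col1a2 fell (log2 fold change -1.25, SE 0.27, adjusted p = 0.0245). Of 18 genes 1 rose, 3 fell and 14 did not pass (1 higher and 5 lower adjusted over the list alone). Fibrosis genes were called lower as a list (adjusted p = 0.00929), but not with an estimated correlation (adjusted p = 0.427). Their scores were -0.683, -0.12 and -0.64 in KO libraries 1 to 3, where KO library 2 lay within the WT range (-0.218 to 0.159). Among stellate cell markers Dcn, the proteoglycan decorin (0.96), rose. Their list of 14 had 2 higher, 1 lower and 11 not passing, with equal counts adjusted over the list alone, and was not called (adjusted p = 0.500). Among erythroid genes Alas2, which starts heme synthesis in red cells (log2 fold change -2.31, SE 0.24, adjusted p = 0.00148), and the beta-globin Hbb-bs (-1.07) fell. Of 8 tested 0 rose, 4 fell and 4 did not pass (6 lower adjusted over the list alone), and globin copies share reads. Their list was called lower (adjusted p = 0.00146; adjusted p = 0.344 with an estimated correlation). Cholangiocyte markers gave 1 lower and 6 not passing of 7 (2 lower adjusted over the list alone). Camera did not call that list (adjusted p = 0.117), while fry called it lower (adjusted p = 0.00466). Lymphocyte, neutrophil and adipose, pancreas and muscle markers had 3, 2 and 2 genes tested, too few for a list test. The share of reads outside genes was also higher in the 3 KO libraries (7.77% to 9.65%) than in the 3 WT libraries (6.13% to 6.92%), and so was the mitochondrial share of gene counts (8.09% to 10.15%, against 6.3% to 8.02%). Without KO library 1 the fibrosis list (adjusted p = 0.056) and without KO library 2 the endothelial list (0.0716) were not called. Calls lost without at least WT library 2 or 3 were those of Clec4f, Flt4, Cdh5, Col1a2, Dcn and Hbb-bs (adjusted p up to 0.137, for Cdh5).

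Some genes of liver zones also changed at 4 weeks. Cyp2f2, a periportal cytochrome P450, fell (log2 fold change -2.19, SE 0.22, adjusted p = 0.00126; n = 3 per group), and so did Ctsc, a lysosomal protease (log2 fold change -1.63, SE 0.23, adjusted p = 0.00603). The other 5 periportal genes that passed, Hal, Gls2, Arg1, Cps1 and Aldh1b1, rose (1.02 to 1.89). That made 5 higher, 2 lower and 8 not passing of 15 (7 higher and 2 lower adjusted over the list alone), without a list call (adjusted p = 0.0560). Of 14 pericentral genes 2 rose, 2 fell and 10 did not pass (3 higher and 3 lower adjusted over the list alone; list adjusted p = 0.613). Cyp2c37, a cytochrome P450, rose (log2 fold change 1.65, SE 0.34, adjusted p = 0.0214) and Glul, glutamine synthetase, fell (log2 fold change -1.16, SE 0.24, adjusted p = 0.0225). Bex4 (log2 fold change 3.04, SE 0.39, adjusted p = 0.00434) and Lpl, lipoprotein lipase (log2 fold change 1.92, SE 0.38, adjusted p = 0.0186), rose in the oncofetal and tumour list. Of its 15 genes 5 rose, 1 fell and 9 did not pass (6 higher and 1 lower adjusted over the list alone). This list was called higher (adjusted p = 0.0183) but not with an estimated correlation (adjusted p = 0.416). None of 18 cell cycle genes passed in edgeR, over all genes or adjusted over the list alone (list adjusted p = 0.0843). Of 18 circadian genes 1 rose, 0 fell and 17 did not pass (0 adjusted over the list alone; list adjusted p = 0.405). The clock gene Arntl, which swings with the time of day, read 40.03, 5.09 and 3.02 CPM in the WT libraries and 45.9, 1.61 and 10.9 CPM in the KO libraries. The score of this oncofetal and tumour list was -0.042, 1.135 and 0.649 in KO libraries 1 to 3 (WT -0.128 to 0.156). Without KO library 2 the oncofetal and tumour list was not called (adjusted p = 0.0597). The cell cycle list was called lower without WT library 1 (adjusted p = 0.00306) or KO library 2 (1.79e-05) or 3 (0.0147). The periportal list was called higher without WT library 1 (0.0458) or KO library 1 (0.0160) or 2 (0.0252). Cyp2c37, Glul and Lpl lost their calls without WT library 2 or 3 (adjusted p up to 0.104, 0.108 and 0.0911).

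In total 1200 of 11144 genes tested at 4 weeks passed in edgeR, 576 higher and 624 lower in KO, and 890 of them changed by at least 1 on the log2 scale. Among 26 lists, 14 were called by camera, 5 higher and 9 lower, of which 1 held with an estimated correlation. Fry, which makes no reference to other genes, called 8 lists, with sulfation higher (adjusted p = 0.00466). It called male-biased (0.00139), bile acid transport (0.00216), glucuronidation (0.00466) and interferon response genes (0.00466) lower. Markers of cholangiocytes (0.00466), erythroid cells (0.0293) and macrophages (0.0362) were also lower by fry. The count moved with single libraries, to 689, 234 and 184 genes without WT library 1, 2 or 3, to 2012 without KO library 1 and to 429 without KO library 3. It was 2048 without the filter on low counts and 537 with the replicate number as a block. Whether the numbers pair the samples is not known.

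At 8 weeks the same question was asked of 4 WT and 6 KO livers, and the KO livers differed widely from one another. Apart from Slc10a1, 3 genes passed in edgeR. Tymp, thymidine phosphorylase, rose from 13.3 ± 3.90 to 52.2 ± 12.5 CPM in 6 of 6 KO libraries (log2 fold change 1.99, SE 0.23, adjusted p = 0.0156; n = 4 and 6). The predicted genes Gm17167 (-3.17, adjusted p = 0.0119) and Gm5859 (-3.28, adjusted p = 0.0345) fell, both named after their values were seen. Sult2a1 stood at 0.0966 CPM in WT and 149 ± 181 CPM in KO, with 5 of 6 KO libraries above the highest WT library (adjusted p = 0.474). Sult1e1 stood at 0.629 and 203 ± 218 CPM, again 5 of 6 (adjusted p = 0.474). Of 19 sulfation genes none passed over all genes and 8 were higher and 2 lower adjusted over the list alone, with the list not called (adjusted p = 0.169) except without KO library 3 or 4, where it was called higher (0.0325 and 0.0341). Cyp2b10 (0.473 CPM in WT and 29.7 ± 25.9 CPM in KO; log2 fold change 5.95, SE 1.45, adjusted p = 0.474) was above WT in 4 of 6 KO libraries, and so was Slco1a4 (adjusted p = 0.474). Mup20 (1617 ± 591 and 1173 ± 1787 CPM) and Elovl3 (54.6 and 55.5 ± 90.4 CPM) were below all WT libraries in 4 KO libraries and above all of them in 2. Cyp7a1 had 669 ± 231 CPM in WT and 261 ± 207 CPM in KO, with 5 of 6 KO libraries below WT (log2 fold change -1.35, SE 0.74, adjusted p = 0.505). Nr0b2 was above WT in 5 of 6 (1.15, SE 0.44, adjusted p = 0.474). Adjusted p was 0.606 for Sult2a8, 0.474 for Sult3a1, 0.543 for Papss2, 0.778 for Cyp8b1, 0.635 for Cyp27a1 and 0.836 for Abcb11. It was 0.474 for Abcc4, 0.654 for Slco1a1, 0.594 for Slco1b2, 0.572 for Nr1h4 and 0.474 for Cyp3a11. The clock gene Arntl stood at 44.9 and 43.7 CPM in KO libraries 1 and 2, 1.8 to 4.77 CPM in the other 4 and 1.39 to 2.57 CPM in WT. The most abundant gene of a library took 12.63% to 14.29% of gene counts in KO libraries 1, 2, 5 and 6, 4.84% and 6.22% in KO libraries 4 and 3 and 5.72% to 6.74% in WT. The mitochondrial share of gene counts was 7.35%, 4.88%, 5.69%, 5.8%, 5.9% and 5.53% in KO libraries 1 to 6 and 4.7% to 5.13% in WT. Tymp lost its call without WT library 1, 2 or 3 or KO library 5 or 6 (adjusted p up to 0.135).

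The gene lists at 8 weeks were tested on the same libraries, and 12 of 28 were called by camera, 9 higher and 3 lower in KO. None of the 12 held with an estimated correlation (adjusted p = 0.607 for each). Male-biased genes were called lower as a list, with a fold change below 0 for all 25 and a median of -0.78 (adjusted p = 1.98e-11). Female-biased genes were called higher, with a median of 1.86 over 22 genes, 6 of them higher adjusted over the list alone (adjusted p = 3.31e-09). KO libraries 3 and 4 did not share these differences. Their male-biased scores of 0.619 and 0.701 lay above all WT libraries (-0.186 to 0.245) and their female-biased scores of -0.561 and -0.358 below them (-0.231 to 0.31). The other 4 KO libraries had scores of -5.484 to -4.59 and 2.972 to 3.377. In CAR and PXR targets the 6 KO libraries scored 1.332, 0.685, -0.27, 0.203, 0.413 and 0.795 (WT -0.13 to 0.141). Targets of CAR and PXR (25 genes, 6 higher adjusted over the list alone; adjusted p = 0.00129), cholesterol synthesis (0.00779), NRF2 targets (0.0136) and oncofetal and tumour genes (7.05e-04) were called higher. Fibrosis (0.00154), cell cycle (0.00196), macrophage (0.0106) and erythroid genes (0.00789) were called higher too, and interferon response (0.00153) and glucuronidation genes (0.0240) lower. Other called lists also rested on some of the 6 KO libraries. Erythroid genes scored 1.648, 1.687, -1.011, 0.016, 0.151 and 1.455 (WT -0.368 to 0.221), interferon response -1.002, -0.322, 0.161, 0.117, -0.045 and -0.891 (WT -0.088 to 0.153) and cell cycle 0.84, 1.168, -0.411, 0.114, 0.531 and -0.109 (WT -0.226 to 0.224). Cholesterol synthesis scored 0.735, 0.783, -0.231, 0.024, -0.319 and 0.623 (WT -0.076 to 0.093). In glucuronidation, fibrosis, NRF2 target, oncofetal and tumour and macrophage genes KO libraries 3 and 4 did not lie beyond all WT libraries in the direction called. In the called lists other than the female-biased genes and the CAR and PXR targets, no member passed adjusted over the list alone. The lists not called were bile acid synthesis (adjusted p = 0.0760), transport (0.401) and signalling (0.382), fatty acid synthesis (0.321) and oxidation (0.157), acute phase (0.111), endoplasmic reticulum stress (0.869) and circadian genes (0.0687; 1 higher and 1 lower adjusted over the list alone). Markers of cholangiocytes (0.169), lymphocytes (0.594), neutrophils (0.879), endothelium (0.0760), stellate cells (0.0760) and pericentral (0.594) and periportal hepatocytes (0.243) were not called either, and 3 adipose, pancreas and muscle markers were too few. Single libraries ended the calls of NRF2 targets (without WT library 4, adjusted p = 0.0758) and of cell cycle and cholesterol synthesis (without KO library 2, 0.0599 and 0.0615). The same held for glucuronidation (without WT library 3 or KO library 2 or 6, up to 0.0831) and macrophage genes (without WT library 2, 3 or 4, up to 0.107). Other lists gained a call when 1 library was left out. Lower were acute phase (without WT library 3, adjusted p = 1.03e-05, KO library 1, 0.0236, or KO library 2, 0.0112), circadian genes (WT library 1, 0.0342, KO library 1, 0.0180, or KO library 6, 0.0432) and bile acid synthesis (WT library 1, 0.0342, KO library 3, 0.0473, or KO library 4, 0.0476). Higher were stellate markers (WT library 1, 0.0395, WT library 3, 0.0103, WT library 4, 0.0479, or KO library 3, 0.00404) and endothelial markers (WT library 3, 0.0486, KO library 3, 0.0473, or KO library 4, 0.0362). Fatty acid oxidation (KO library 2, 0.0137, or KO library 6, 0.0419) and cholangiocyte markers (WT library 1, 0.00385) were called higher as well.

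Over all genes at 8 weeks, 4 of 14522 passed in edgeR, 1 higher and 3 lower, against 1517 at an unadjusted p under 0.05 and 109 in DESeq2 (75 higher, 34 lower). The count was 1 without WT library 1, WT library 3 or KO library 5, 2 without WT library 2 or KO library 6, and 0 with the replicate number as a block. KO libraries 5 and 6 have no WT library of the same number, so they add nothing to the comparison in the block fit.

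At 20 months the comparison asks whether the KO effect is present in old mice. No gene of 13966 passed in edgeR (772 at an unadjusted p under 0.05, smallest adjusted p 0.421), and 53 passed in DESeq2, 7 higher and 46 lower in KO. Sult1e1 (53.8 ± 87.4 CPM in WT and 14.8 ± 4.91 CPM in KO, n = 3 each; adjusted p = 0.828), Mup20 (1109 ± 876 and 1035 ± 223 CPM) and Elovl3 (73 ± 63.9 and 126 ± 19.5 CPM) overlapped between genotypes. Sult2a1 (0.148 and 0.0424 CPM) and Sult3a1 had too few counts to be tested. Nr0b2 was at 5.13 CPM in WT and 13.3 CPM in KO (log2 fold change 1.39, SE 0.35, adjusted p = 0.821). Adjusted p was 0.949 for Cyp7a1, 0.903 for Cyp8b1, 0.892 for Cyp27a1, 0.821 for Abcb11, 0.821 for Abcc4, 0.825 for Slco1a1, 0.828 for Slco1a4 and 0.883 for Slco1b2. It was 0.857 for Nr1h4, 0.828 for Cyp2b10, 0.981 for Cyp3a11, 0.841 for Sult2a8 and 0.878 for Papss2. Without WT library 3, 71 genes passed, 7 higher and 64 lower.

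Acute-phase genes, which hepatocytes secrete in inflammation, set WT libraries 1 and 2 of 20 months apart from the other 4 libraries of that age. Saa1, a serum amyloid, read 47489, 22338 and 213 CPM in WT and 160.3 to 259 CPM in KO. Lcn2, lipocalin, read 1755, 587 and 14.8 CPM in WT and 12.3 to 18.4 CPM in KO. S100a9, a neutrophil protein, read 1709, 166 and 4.11 CPM in WT and 3.40 to 6.38 CPM in KO. The acute-phase list was called lower in KO, with 14 of 28 genes lower adjusted over the list alone, none over all genes and a median log2 fold change of -1.57 (adjusted p = 2.99e-24; adjusted p = 0.644 with an estimated correlation). Neutrophil markers were called lower, 11 of 13 adjusted over the list alone, with a median of -6.64 (adjusted p = 1.92e-13; adjusted p = 0.644 with an estimated correlation). Also called lower were cell cycle (adjusted p = 2.17e-08), macrophage (1.27e-06), endoplasmic reticulum stress (0.00504) and oncofetal and tumour genes (0.0240). Bile acid signalling (adjusted p = 9.07e-06), fatty acid synthesis (3.69e-09), fatty acid oxidation (1.31e-04), CAR and PXR targets (0.00789), female-biased genes (0.0165) and glucuronidation genes (0.0219) were called higher, in all 12 of 28 lists. With an estimated correlation none of the 12 was called, with adjusted p from 0.644 to 0.871, and no member outside the acute-phase and neutrophil lists passed adjusted over its list alone. Without WT libraries 1 and 2, a setting chosen after their values were seen, 0 genes passed and 11 lists were called. CAR and PXR targets (adjusted p = 0.00742), glucuronidation (4.58e-04) and fatty acid oxidation genes (8.12e-04) were then called lower, and cell cycle (0.0343) and macrophage genes (0.0152) higher, each the opposite of the direction with all 6 libraries.

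**Figure D4:**
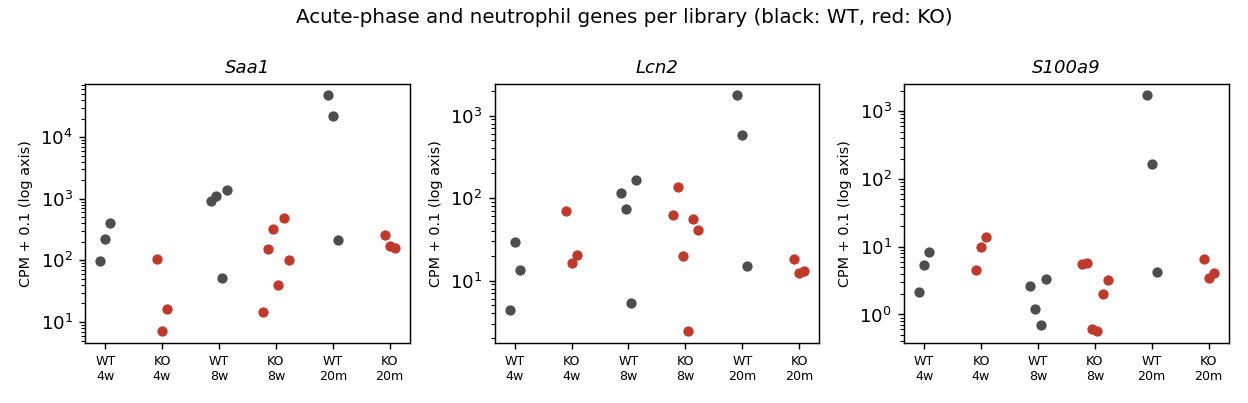
Levels of the acute-phase genes Saa1 and Lcn2 and of the neutrophil gene S100a9 in each of the 22 libraries, as CPM plus 0.1 on a log axis, 1 point per library, WT in black and KO in red. WT libraries 1 and 2 of 20 months lie above the other 20 libraries for all 3 genes.

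The other lists at 20 months were not called. Sulfation had an adjusted p of 0.701, bile acid synthesis 0.146, bile acid transport 0.414, cholesterol synthesis 0.414, male-biased genes 0.413, interferon response 0.563, fibrosis 0.658, NRF2 targets 0.414 and circadian genes 0.0737. For markers of cholangiocytes it was 0.203, of lymphocytes 0.810, of endothelium 0.810, of stellate cells 0.387, of erythroid cells 0.0732, of pericentral hepatocytes 0.459 and of periportal hepatocytes 0.733, while adipose, pancreas and muscle markers were too few. The median, mean and test of a list differed in sign for 14 lists over the 3 ages, 0 of which were called. KO library 1 of 20 months held 14.72% of its reads outside genes, against 7.0% to 8.52% in WT. The mitochondrial share of gene counts was 4.68% to 6.91% in KO and 2.8% to 4.63% in WT at 20 months. Single libraries ended the calls of CAR and PXR targets (without WT library 1 or KO library 3, adjusted p = 0.77 and 0.283), glucuronidation (0.474 and 0.312) and oncofetal and tumour genes (0.474 and 0.306, and 0.134 without KO library 2). They also ended those of stress genes (without WT library 2 or 3, adjusted p = 0.112 and 0.0787), fatty acid oxidation (without WT library 2, 0.188) and female-biased genes (without WT library 2, KO library 1 or KO library 3, up to 0.49). Lists not called with all 6 libraries gained a call when 1 library was left out, in both directions for 2 of them. Cholesterol synthesis was called lower without WT library 1 (adjusted p = 0.00595) and higher without WT library 2 (0.00238) or KO library 3 (7.06e-04). Male-biased genes were called lower without WT library 1 (0.00221) and higher without WT library 2 (0.00244). Called higher were interferon response (without WT library 1, 5.42e-04, or KO library 2, 3.41e-07), bile acid synthesis (WT library 3, 0.00168, or KO library 1, 0.0112) and circadian genes (WT library 3, 0.0478, or KO library 1, 5.53e-05). So were NRF2 targets (WT library 3, 0.00138), periportal markers (KO library 1, 0.0248) and lymphocyte markers (KO library 3, 0.00237). Called lower were fibrosis genes (KO library 1, 0.0106), cholangiocyte markers (WT library 3, 0.0203) and erythroid markers (WT library 1, 0.0248, WT library 3, 0.0150, KO library 2, 0.00897, or KO library 3, 0.00477).

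Whether the KO effect differed among ages was tested in 1 model of all 22 libraries, and 258 of 15877 genes passed the joint test in edgeR. Mpv17l, a peroxisomal and mitochondrial membrane protein, had KO effects of 2.32 (SE 0.20) at 4 weeks, 0.41 at 8 weeks and -0.22 at 20 months (joint adjusted p = 0.00253). Trdmt1, an RNA methyltransferase, had 3.03 (SE 0.36), 0.53 and -0.15 (adjusted p = 0.00411). Plod3, a collagen-modifying lysyl hydroxylase, had -1.91 (SE 0.28), -0.20 and 0.08 (adjusted p = 0.00418). The kinase gene Map3k10 had -1.78, -0.11 and 0.19 (adjusted p = 0.00418), the dystrophin gene Dmd 1.55, -0.06 and 0.44 (0.00482) and the zinc finger gene Zfp703 -1.70, 0.04 and 0.01 (0.00516). For Slc10a1 (0.122) and Mup20 (0.235) the joint adjusted p did not pass. By pairs of ages, 52 genes differed between 8 and 4 weeks (25 higher, 27 lower), 718 between 20 months and 4 weeks (318 higher, 400 lower). None differed between 20 months and 8 weeks in edgeR (0 genes), where 1798 had an unadjusted p under 0.05 and DESeq2 called 143. The 4-week libraries were paired-end and the others single-end per the file names, and the 8-week libraries carry another run label, so age and sequencing batch cannot be told apart.

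These counts moved with single libraries and settings. The joint count went from 26 without WT 4-week library 3 to 1081 without WT 20-month library 3, and it was 7 with the replicate number as a block and 1226 in DESeq2. Over 1.5 times fewer joint genes (46 to 134) were also found without WT 4-week library 2, KO 4-week library 2 or 3, any of the WT 8-week libraries, WT 20-month library 1 or 2 or any KO 20-month library, and 695 without KO 8-week library 1. The 8-week against 4-week count ranged from 8 to 270, the highest without KO 8-week library 1, and was 110 without WT 20-month library 1. The balance of 25 higher and 27 lower moved with the scaling, to 9 and 21 with DESeq2 size factors and 6 and 17 with library size alone. Only leaving out WT or KO 4-week library 1, WT 20-month library 3 or KO 20-month library 1 kept it within 1.5 times of 52. For 20 months against 4 weeks the count was 247 and 164 without WT 4-week library 2 or 3, and 1405 without KO 8-week library 1. It was 237, 397 and 1243 without WT 20-month library 1, 2 or 3, and 446, 449 and 338 without KO 20-month library 1, 2 or 3. For 20 months against 8 weeks it was 517 without WT 20-month library 3.

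Shared direction between ages was strongest for 4 and 8 weeks. Of 1194 genes called at 4 weeks and tested at 8 weeks, 1079 (90.4%) had a fold change of the same sign at 8 weeks. Across 11068 genes the fold changes had a Pearson r of 0.53 and a Spearman rho of 0.51. Among genes at an unadjusted p under 0.05, 300 were higher at both ages where 107 were expected of independent lists (one-sided Fisher exact p = 2.16e-73, for more overlap), and 166 were lower at both where 59.5 were expected (one-sided Fisher exact p = 1.17e-39). Between 4 weeks and 20 months, 417 of 1176 called genes (35.5%) kept the sign, with an r of -0.10 and a rho of -0.15 across 11054 genes. The corresponding overlaps were 20 genes higher (25.7 expected, one-sided Fisher exact p = 0.911) and 52 lower (50.9 expected, one-sided Fisher exact p = 0.459). Between 8 weeks and 20 months 18 were higher (14.7 expected, one-sided Fisher exact p = 0.217) and 34 lower (18.4 expected, one-sided Fisher exact p = 4.41e-04), while the fold changes had an r of -0.12 and a rho of -0.17 across 13314 genes. Of genes called at 8 weeks 2 were tested at 20 months, and 2 kept the sign. Genes are not independent replicates, so these p-values describe overlap across genes. The fold changes of 20 months include the distance of WT libraries 1 and 2 from the other libraries of that age. Acute-phase scores there were 1.23, 0.488 and -1.717 in WT libraries 1 to 3 and -1.847, -1.696 and -1.676 in KO. A lost or reversed KO effect in old mice therefore cannot be read from the sign shares and correlations with 20 months. No gene passed in the same direction at all 3 ages in edgeR, out of 11026 tested, against 15 at an unadjusted p under 0.05. In DESeq2 2 genes did, Slc10a1 and, named after its values were seen, Hamp2, a hepcidin gene (4.56, 4.10 and 2.60 at 4 weeks, 8 weeks and 20 months).

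The WT livers alone were compared between ages, in which age cannot be told apart from the sequencing batch. From 4 to 8 weeks Cyp4a14, a fatty acid omega-hydroxylase under PPAR-alpha, fell from 8989.7 ± 4516 (n = 3) to 85.9 ± 71.2 CPM (n = 4; log2 fold change -6.75, SE 0.74, adjusted p = 4.42e-05). The mitochondrial gene mt-Co3, a cytochrome oxidase subunit (-5.76, SE 0.14), and the ribosomal pseudogene Rpl23a-ps3 (-7.15, SE 0.16) fell too. Mitochondrial genes as a whole did not share the fall of mt-Co3, since their share of WT gene counts was 6.3% to 8.02% at 4 weeks and 4.7% to 5.13% at 8 weeks. In the KO libraries of 8 weeks mt-Co3 read 0.97 to 1.84 CPM. Whether its fall comes from the read layout or counting was not tested. Rpl21-ps10, another ribosomal pseudogene, went from 14.2 CPM to 0 counts, at least 448-fold lower against a floor of 3 counts over the group. Moxd1, a monooxygenase-like protein, and Mup-ps20, a urinary protein pseudogene, went from 0 counts to 36.8 and 3.08 CPM, at least 213-fold and 17.8-fold higher. Counts over the microRNA gene Mir6236 (10.05, SE 0.29) and the mitochondrial tRNA mt-Tc (6.66, SE 0.21) rose, and whether these reads come from the named RNAs was not tested. From 8 weeks to 20 months S100a9 rose (log2 fold change 8.30, SE 1.77, adjusted p = 0.00520) on the 2 WT libraries given above. The mitochondrial tRNAs mt-Te and mt-Ts1 rose (10.30 and 9.31), and mt-Ty went from 0 counts to 7.06 CPM, at least 223-fold higher. Counts over the leucyl-tRNA synthetase gene Lars2 fell from 4834 ± 749.9 to 108 ± 15.7 CPM (log2 fold change -5.53, SE 0.26). The ribosomal RNA gene CT010467.1 fell by a similar amount (-5.56, SE 0.38). Whether the reads counted for Lars2 come from its own transcript was not tested. Lrp2, an endocytic receptor, and Acsm2, a medium-chain acyl-CoA synthetase, both abundant in kidney, were called lower, and their 8-week level came from WT library 1 (130.3 and 99.4 CPM). In edgeR 7449 of 14003 genes passed between 4 and 8 weeks (3850 higher, 3599 lower) and 7802 of 14322 between 8 weeks and 20 months (3968 higher, 3834 lower). With a fold of at least 1 on the log2 scale these were 3193 and 4223. With library size as the sole scaling the median fold between 4 and 8 weeks shifted by 0.25, and the share of called genes that were higher went from 51.7% to 68.5%. The call of Lrp2 was lost without WT 8-week library 1 or any WT 20-month library (adjusted p up to 0.123), and that of Acsm2 without any WT 20-month library (up to 0.0728).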

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

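All tests of explanations in this part were chosen after the results were seen.

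Male-biased liver genes were lower in the KO livers of 4 weeks, with 21 of 24 called. Female animals among the KO samples are argued against by the Y-linked gene Ddx3y, whose lowest KO library stood at 153.72 CPM. An exchange of genotype labels is argued against by Slc10a1, whose lowest WT value was 2.33 times the highest KO value. A scaling set by a few abundant genes is argued against by the list's median log2 fold change of -3.42 with library sizes and factors taken without the 50 most abundant genes. The remaining explanation by genotype is a hypothesis, since litter, body weight and feeding are not in the labels and could differ between the 3 WT and 3 KO animals.

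The KO libraries of 8 weeks lay far apart in male-biased genes, at scores of -5.16, -5.21, 0.619, 0.701, -4.59 and -5.48 against -0.186 to 0.245 in WT. WT samples among those labelled KO are argued against by Slc10a1, whose lowest WT value was 4.64 times the highest KO value. Depth is argued against, since gene count totals of the KO libraries differed by a factor of 1.12, less than those of the WT libraries. A scaling set by a few abundant genes is argued against, since without the 50 most abundant genes the highest score of the 4 KO libraries below WT was -4.48. Time of day, as a straight-line trend with the clock gene Arntl, is argued against as the whole cause. Within the other 5 groups the score changed by -0.102 per doubling of Arntl (95% interval -0.343 to 0.139). That allows a decrease to -1.63 at most in the 4 KO libraries below WT, and their scores were lower. Another dependence on the time of day stays open. Differences between KO animals, which may come from body condition or feeding, stay open and were not tested.

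Acute-phase and neutrophil genes were high in WT libraries 1 and 2 of 20 months. Neutrophils or blood as the whole cause are argued against by hepatocyte transcripts: summed Saa1 and Saa2 levels were at least 49.9 times the summed S100a8 and S100a9 levels in both libraries. An exchange of labels between genotypes is argued against by Slc10a1, whose lowest WT value was 1.499 times the highest KO value. That margin is smaller than at the younger ages. The limit set for it was also lower than the 1.5 required at those ages, which 1.499 does not pass. Inflammation in these 2 animals is a candidate explanation that stays open, as does a difference in the handling of the tissue.

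Single samples far from their group were looked for in 148 pairs of a named gene and a group of 4 or 6 libraries, and 14 were found, where chance alone gives about 1 in 20. The values below are the gap to the nearest library over the range of the group. In WT of 8 weeks, library 1 was far from the others for Slc4a9 (0.949; 1.58 CPM), Cyp2c37 (0.986; 94.1 CPM), Lrp2 (0.989; 130 CPM) and Acsm2 (0.985; 99.4 CPM), and library 4 for Gsta2 (0.873; 2.42 CPM) and Cyp2f2 (0.846; 630.4 CPM). In KO of 8 weeks, library 1 was far for Pdk4 (0.856; 267 CPM) and Bex4 (0.667; 10.1 CPM) and library 2 for Sult3a1 (0.711; 29.1 CPM) and, on the low side, mt-Co3 (0.632; 0.97 CPM). Library 3 was far for Serpina4-ps1 (0.799; 356 CPM), Saa4 (0.630; 818 CPM) and Moxd1 (0.850; 187 CPM), and library 4 for Map3k10 (0.660; 11.2 CPM).

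The joint test of the KO effect among the 3 ages was passed in edgeR by 11 named genes. Dmd, Map3k10, Mpv17l, Plod3, Trdmt1 and Zfp703 were named for their small adjusted p in this same test, so their passing adds no support. Flt4, Irf7 and Sult1b1 were named for their small adjusted p in KO against WT at 4 weeks. Mir6236 and S100a9 were named for large changes between ages in WT. These choices used the same libraries, so the passing of these genes is no independent support either. For S100a9 the test includes the high levels in WT libraries 1 and 2 of 20 months. Of 60 splits of the libraries, 7 gave a joint count as large as the real one, which is included. Adjusted p was 0.00482 for Dmd, 0.0489 for Flt4, 0.0408 for Irf7, 0.00418 for Map3k10, 0.0181 for Mir6236, 0.00253 for Mpv17l, 0.00418 for Plod3, 0.0369 for S100a9, 0.0408 for Sult1b1, 0.00411 for Trdmt1 and 0.00516 for Zfp703. Reads outside genes, which no comparison used, were above every WT library of the age in the 3 KO libraries of 4 weeks (9.65%, 7.87% and 7.77%, against 6.13% to 6.92%) and in KO library 1 of 20 months (14.72%, against 7.0% to 8.52%).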

How the results depend on the processing

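The fit with group weights and the 20-month comparison without WT libraries 1 and 2 were chosen after the data were seen; the other alternatives were fixed before. Where a count moved, the cause was not tested, except that leaving out libraries leaves fewer samples. Named genes gave 120 results and 1945 values under alternatives, of which 1804 stayed on the same side of the threshold, 128 fell below it and 13 rose past it. No called gene changed sign (0 values), while 26 values of genes not called did. Lists gave 82 results and 1124 values: 936 stayed on the same side of the threshold, 109 lost and 74 gained a call, and 5 were reversed. These were CAR and PXR targets (adjusted p = 0.00742), glucuronidation (4.58e-04), fatty acid oxidation (8.12e-04), cell cycle (0.0343) and macrophage genes (0.0152) at 20 months without WT libraries 1 and 2.

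Without the low-count filter the counts were 2048 (KO at 4 weeks), 18 (KO effect, 8 against 4 weeks, 10 higher and 8 lower), 404 (20 months against 4 weeks) and 14 (20 months against 8 weeks). With the replicate number as a block they were 537 at 4 weeks, 0 at 8 weeks, 7 for the joint test of ages, and 2, 122 and 1 for the pairs of ages in that order. Whether the numbers pair the samples is not known. Deviations of samples with the same number correlated by -0.07, 0.02 and 0.01 at 4 weeks. The values were -0.00, -0.16, 0.07 and -0.33 at 8 weeks and 0.44, 0.03 and 0.46 at 20 months. At 20 months the pairs numbered 1 and 3 were each the closest between genotypes for both libraries. So few libraries cannot settle whether samples were paired. DESeq2 called 109 genes at 8 weeks, 53 at 20 months, 1226 jointly, 378, 1555 and 143 by pairs of ages and 2 at all 3 ages. For 8 against 4 weeks the count was 30 with DESeq2 size factors (9 higher, 21 lower), 23 with library size alone (6 and 17), 18 with robust dispersions (7 and 11) and 18 without the 50 most abundant genes (7 and 11). A fold of at least 1 on the log2 scale left 3193 and 4223 genes in the WT age comparisons. Lists called with an estimated correlation were 1, 0 and 0 at 4 weeks, 8 weeks and 20 months, and 8, 0 and 0 by fry. With group weights 1135, 4 and 0 genes were called at the 3 ages.

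Leaving out 1 library gave 184 to 2012 genes at 4 weeks, 1 to 5 at 8 weeks, 0 to 71 at 20 months and 26 to 1081 for the joint test. It gave 8 to 270, 164 to 1405 and 0 to 517 for the pairs of ages, and 0 at all 3 ages. The WT age counts of 6501 to 7482 and 6433 to 8809 and the list counts of 13 to 15, 11 to 16 and 11 to 16 stayed within 1.5 times. Depth was lowest at 4 weeks (5496425 to 6956124 counts), which left 11144 genes to test there against 14522 and 13966.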

Other observations

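The tests in this part were chosen after the results were seen. Igfbp1, a hepatic binding protein of insulin-like growth factors that rises in fasting, was higher in KO livers of 4 weeks, at 404 ± 64.1 CPM in WT and 4708 ± 2896 CPM in KO (log2 fold change 3.58, SE 0.46, adjusted p = 0.00434 in edgeR; n = 3 per group). At 8 weeks it read 7797, 1829.9, 49.9, 20.9, 526 and 718 CPM in KO libraries 1 to 6 and 58.2 to 268 CPM in WT. Asns, asparagine synthetase, a target of the stress factor ATF4, rose at 4 weeks (log2 fold change 2.74, SE 0.26, adjusted p = 8.83e-04), as did Atf4 itself (1.00, SE 0.23, adjusted p = 0.0294). The urea cycle genes Cps1 (1.25, SE 0.30, adjusted p = 0.0345) and Arg1 (1.31, SE 0.30, adjusted p = 0.0296) rose with them, while Mlxipl (-1.31), which acts in glucose use and lipid synthesis, fell.

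In the KO livers of 8 weeks the scores of several lists varied together over single libraries. Male-biased scores were -5.16, -5.21, 0.619, 0.701, -4.59 and -5.48 in libraries 1 to 6, female-biased scores 3.02, 2.97, -0.561, -0.358, 3.38 and 3.1, and sulfation scores 2.59, 2.60, 0.003, -0.148, 1.69 and 2.92. Macrophage scores were 0.569, 0.765, -0.296, -0.336, 0.48 and 0.747 (WT -0.242 to 0.537) and fibrosis scores 0.658, 0.614, -0.218, -0.055, 0.65 and 0.532 (WT -0.215 to 0.271). Cps1 read 15337, 10942, 7669, 7022, 11718 and 11199 CPM in the same libraries, against 6841 to 7846 CPM in WT. Arntl read 44.9, 43.7, 2.39, 1.80, 4.77 and 3.81 CPM.

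A first hypothesis was that KO livers of 8 weeks differ from one another more than WT livers do. The male-biased score had an SD of 2.99 in KO and 0.188 in WT, and an exact one-sided permutation of the variance ratio over all 210 splits gave p = 0.00476, the smallest these splits allow. The score was chosen because it showed the spread, so this p restates the observation and decides nothing about the hypothesis. A second hypothesis was that the KO effect of 4 weeks is shared at 8 weeks. Of 1194 genes called at 4 weeks, 90.9% had the same direction in mean log2 CPM at 8 weeks, and an exact one-sided permutation over the 210 splits of the 8-week libraries gave p = 0.00476, again the smallest possible. The highest other split gave 90.5%, so the margin was small, and it may rest on the KO libraries that stand apart.

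Other splits of the same libraries into groups of the same sizes were fitted for each count. For KO against WT at 4 weeks and at 20 months 10 splits exist, too few for a share under 0.05. The real split was the only 1 of 10 with 1200 genes (highest other 0) and with 14 lists (highest other 13) at 4 weeks; at 20 months the real count was 0 genes, which all 10 splits reach by construction (highest other 0), and 8 of 10 gave at least 12 lists (highest other 18). At 8 weeks 2 of 100 splits gave at least 4 genes. The targeted gene Slc10a1 is 1 of the 4 real calls and favours the real split by design. The splits therefore do not exclude chance for the other calls. The highest other count was 3866 genes, from a split that sets KO libraries 1, 2, 5 and 6 against the other 6 libraries. That points to a structure of the samples. At least 12 lists were called in 29 of 100 splits (highest other 21), so chance was not excluded for the lists. The WT age counts were reached by 1 of 35 splits each (7449, highest other 1, and 7802, highest other 0), the smallest share these splits allow. Chance is thereby made unlikely but not excluded. The other splits mix both ages, and so both batches, within a group, so they cannot tell age from batch. For the joint test of ages 7 of 60 splits gave at least 258 genes (highest other 1759), for 8 against 4 weeks 8 of 60 at least 52 (2714), and for 20 months against 4 weeks 3 of 60 at least 718 (1715), so chance was not excluded for these 3 counts. Their high counts in other splits also point to a structure of the samples. The highest joint count and the highest count for 8 against 4 weeks came from different splits, so no single grouping of libraries is named for it. The real count was 0 for 20 months against 8 weeks (all 60 splits, highest other 1569) and for all 3 ages (all 100 splits, highest other 0), so every split reaches it and the splits say nothing about chance.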
